A study of Drosophila melanogaster with 2 samples.

How the data were processed

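The 2 libraries were made from whole embryos of a fly strain that expresses a Rough-eGFP fusion, aged 0 to 24 h, after sonication to 200 to 800 bp, per the labels. Both belong to 1 group and are separate biological replicates per the labels. No input or mock sample was analysed here. The deposited notes name a further input shared by both replicates, and 1 more for the thresholded lists, without stating their roles, and neither was analysed here.

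The authors deposited, for each replicate and for both together, a ranked list of candidate peaks and a thresholded list cut from such a ranking by the irreproducible discovery rate (IDR), on the dm6 build per the labels. The aligner, the peak caller and their versions are not given in the sources used here. The deposited lists give a peak score, whose lowest value was 830 in 3 of the thresholded lists. They also give the authors' signal value per peak, which was used to describe, rank, filter and test peaks within a list and to correlate the replicates. The q value column is deposited as −log10 q and has values slightly below 0 on this log10 scale in the lists over both replicates (down to -0.0416). The ranked lists give, in a deposited column, the −log10 of the global IDR, and every peak of the thresholded lists had at least 2, that is an IDR of at most 0.01. In the ranked lists over both replicates, 16 columns in all, with values of single replicates, were matched to no sample by any label and were not used. The lists hold no read totals, so depth is unknown and the intervals given here cover only the counting of peaks or genes.

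Peaks were placed by their summit. Annotation was Ensembl release 115 (BDGP6 6.54) with transposable elements and pseudogenes left out, and sequence was the Release 6 assembly. Peak ends lay within the length of each arm. Location classes were taken in the order promoter (summit within 500 bp of a start), 5' UTR, CDS, 3' UTR, non-coding exon, intron and intergenic; non-coding exon was added to the planned classes because some summits lay in exons with no coding sequence. Peaks on unplaced sequences (86 of 1969) were left out of the location, signal, gene and motif tests. Candidates are peaks of the ranked list outside the thresholded list.

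Tests were fixed before the data were examined, apart from the choices said here to be later. They were a permutation test of replicate overlap (1 bp, 1000 draws), Fisher's exact test for location, chromosome arm and gene lists, a permutation test of medians (100000 resamples) and an exact McNemar test of 9 words. The word windows were 101 bp long and the flank lay 300 bp to the right. Benjamini-Hochberg adjustment was made within each family at a threshold of 0.05. A gene carried a peak when its start was the nearest protein-coding start. Of the list symbols, *h*, *svb* and *Dl* were matched through synonyms to *hry*, *ovo* and *Delta*. The synonym *Dl* also names *dl*; the rule that leaves out a gene with the same letters in another case was set after a first run and lowered the Notch odds ratio. Intervals of shares are Wilson 95% intervals and those of odds ratios are Woolf 95% intervals. Where a count was 0, a small constant was added to every count before the odds ratio was computed, so it is not a raw ratio.

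Named genes follow a rule fixed beforehand: the nearest gene of the 20 strongest optimal-set peaks, the 10 genes with the most peaks, up to 4 members of each list with a peak that overlaps both replicates' own lists, in order of signal value, and *ro*. A result that this rule would name was left out because it is withheld for evaluation. Alternatives tried were the conservative set, the stronger part of the list by signal, each replicate's own list (leaving out the other replicate), wider promoters, a background of the strongest 20000 candidates, other overlap rules, other gene assignment, 10000 matched random lists, and other motif windows. The other gene assignment, called by gene body below, took summits in a gene or up to 2 kb upstream of it. Leaving out peaks that overlap a stronger candidate, peaks with q above 0.05, and a background of genes with a promoter candidate were chosen after seeing the data.

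The tests were tested on simulated data. A planted share of 42.2% of 1302 peaks gave an overlap of 42.4%, and a planted location odds ratio of 3 in 1900 peaks gave 3.24. None (0) of 200 gene lists with no effect was called. There every gene had the same chance of a peak, so lists of genes with many candidates were not covered. A word planted in 10.6% of 1900 windows gave a difference of 9.79%, and a word planted in 10.7% of 1000 windows lay 9.46% above dinucleotide shuffles. The first of these used summit and flank windows of the same base composition, unlike the data. Analyses used Python 3.11.15, numpy 2.4.6, pandas 2.3.3 and scipy 1.17.1.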

Results

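The data are chromatin immunoprecipitation (ChIP-seq) peak lists for Rough, a homeodomain transcription factor encoded by the *ro* gene and best known for its part in patterning the compound eye. Whole fly embryos aged 0 to 24 h carried a transgene that encodes Rough fused to eGFP, and an antibody against GFP was used for the pull-down. There was 1 group with 2 biological replicates, so no group comparison exists and no control sample was analysed here. The lists hold no read counts, so the sequencing depth is unknown. All coordinates are on dm6.

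Replicate 1 had 1484 thresholded peaks out of 93400 ranked candidate peaks, and replicate 2 had 1113 peaks out of 121684. The larger list over both replicates, called the optimal set, held 1969 peaks, and the smaller, conservative set held 1627. Median peak width in the optimal set was 380 bp. The authors' signal value, given for each peak, ran from 2.27 to 1265 in the optimal set, with a median of 102. The optimal set was 1.21 times the size of the conservative set, and the list of replicate 1 was 1.33 times the size of that of replicate 2. By the q value of each peak, 53.4% of the optimal set lay above 0.05, against 6.94% of the list of replicate 1 and 60.6% of that of replicate 2.

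The strongest peaks lay mainly at promoters. The strongest, with a signal value of 1265, lay at X 2703710 to 2704053, 30 bp upstream of the start of *Ugalt*, which encodes a UDP-galactose transporter. It was followed by peaks nearest to *CG14100* (1073), *mRpL41*, a mitochondrial ribosomal protein gene (1064), *CG7601* (968.7) and *CG11050* (944.4). The next were nearest to *Tcs5* (874.3), *ph-p*, a Polycomb group gene (808), *Art3*, an arginine methyltransferase gene (803), *px* (794.3) and *tara* (787.4). The other 10 of the 20 strongest were nearest to *Adf1*, *Chro*, *CG5611*, *CenG1A*, *PNPase*, *CG18549*, *eIF6*, *GstE13*, *HmgZ* and *CG13323*, with signal values from 632.6 to 784.1. Of these 20 peaks, 15 had their summit at a promoter, and all 20 overlapped a thresholded peak in both replicates. The peak nearest to *tara*, at 3R 16222349 to 16222642, was intergenic and 3152 bp upstream of the gene's start. Those nearest to *CG11050*, *Adf1* and *HmgZ* were intronic, and that nearest to *CG13323* was intergenic.

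Several genes were the nearest gene of 5 or more optimal-set peaks, counting peaks that overlap a stronger candidate. *CHES-1-like*, which encodes a forkhead protein, and *CG43245* were each the nearest gene of 8 optimal-set peaks. *Ids* had 7, and *Tlk*, *Hr4*, a nuclear receptor gene, and *Myo81F* had 6 each. *sbb*, *CG7560* and *CG6163* had 5 each. None of the peaks of *Myo81F* lay in both replicates' own lists, against 5 each of those of *CHES-1-like* and *Ids*. Of the 1447 protein-coding genes with an optimal-set peak, 1150 had 1 peak and 82 had at least 3.

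The replicates marked many of the same places. Of the peaks of replicate 1, 786 of 1484 (53.0%, Wilson 95% interval 50.4 to 55.5) overlapped a peak of replicate 2. In the other direction 758 of 1113 did (68.1%, 65.3 to 70.8). As many peaks drawn from the other replicate's ranked list gave means of 0.931% and 1.71%, and at most 1.82% and 3.05% (permutation test, 1000 draws, one-sided p = 0.001 for each, the smallest that these draws can give). The draws took no account of signal value, and most ranked peaks lay outside the thresholded lists. The test therefore cannot tell why strong peaks are shared. In the optimal set, 773 peaks (39.3%) lay in both replicates' own lists and 396 (20.1%) in neither. Across 1830 optimal-set peaks with a summit in both ranked lists, the signal values had a Spearman rho of 0.48 and a Pearson r of 0.59 on the log10 scale. This is a correlation across peaks of 1 pair of libraries. Peaks are not independent replicates, so no p is given. The peaks were selected for reproducibility by IDR, so rho describes the selected peaks and not all candidates.

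**Figure D1:**
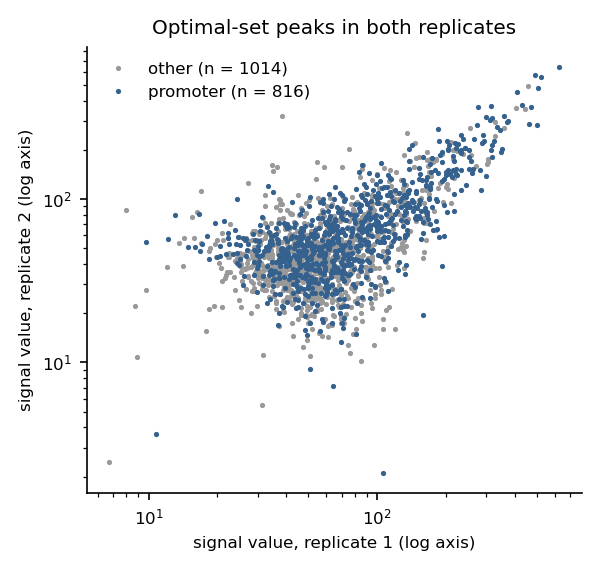
Signal value in replicate 1 (x, log axis) against replicate 2 (y, log axis) for 1830 of 1969 optimal-set peaks. Peaks without a summit in both ranked lists are left out. Promoter peaks are in blue and all others in grey. The 1830 points rise together most clearly at high values, and the Spearman rho over all of them is 0.48.

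Promoters held the largest share of peaks. Summits within 500 bp of an annotated start made up 869 of 1883 peaks on the named chromosome arms (46.2%, 43.9 to 48.4), against 12.8% of the candidate peaks outside the set. The odds ratio was 5.82 (95% interval 5.31 to 6.38; Fisher's exact test, two-sided, Benjamini-Hochberg adjusted p = 6.55e-267). The median distance from the summit of a promoter peak to the nearest start was 147 bp. Coding sequence held 2.18% of peaks against 20.4% of candidates (odds ratio 0.0868, Fisher adjusted p = 4.79e-125), and intergenic sequence 14.5% against 25.7% (odds ratio 0.489, adjusted p = 1.54e-31). Peaks in 3' UTRs were also under-represented (0.743% against 2.13%, odds ratio 0.344, Fisher adjusted p = 6.05e-06). The odds ratio of coding sequence was 0.0336 in the list of replicate 2 and 0.0179 in that of replicate 1, and that of 3' UTRs was 0.167 in the list of replicate 2. Introns held 34.7% of peaks against 37.2% (odds ratio 0.897, Fisher adjusted p = 0.0359), and this call ended against the strongest 20000 candidates (odds ratio 0.99, adjusted p = 0.859) and without peaks that overlap a stronger candidate (odds ratio 0.90, adjusted p = 0.0502), a choice made after seeing the data. Shares in 5' UTRs (0.584% against 0.861%) and non-coding exons (1.12% against 0.775%) did not pass the test (Fisher adjusted p = 0.255 and 0.129).

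**Figure D2:**
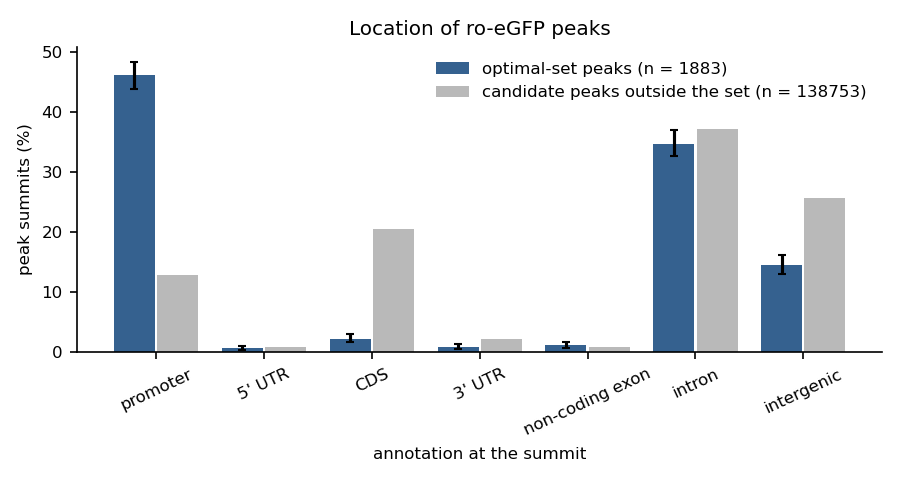
Share of peak summits (%) in each annotation class for 1883 optimal-set peaks (blue, with Wilson 95% intervals) and 138753 candidate peaks outside the set (grey). Promoters hold 46.2% of the peaks and 12.8% of the candidates, and coding sequence 2.18% and 20.4%.

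Promoter peaks were also the stronger ones. Their median signal value was 116 (quartiles 85.4 and 180, n = 869), against 92.8 (73.1 and 126, n = 1014) for the other peaks on the arms. The difference in medians was 23.5 (permutation test, 100000 resamples, two-sided p = 1e-05, the smallest these resamples can give). Promoters held 63.6% of the strongest 500 peaks and 33.4% of the weakest 500. The difference was 8.3 in the list of replicate 2 and 12.5 in that of replicate 1, on the scale of each list.

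Against all candidates outside the set, arms 2L, 2R, 3L, 3R and X differed little. Arm 2L held 18.9% of peaks against 16.9% of candidates (odds ratio 1.14), 2R 16.2% against 18.2% (0.868) and 3R 22.4% against 24.8% (0.878), each with an adjusted p of 0.0348 (Fisher's exact test, two-sided). The X held 17.3% against 17.1% (odds ratio 1.01, Fisher adjusted p = 0.880) and 3L 20.7% against 19.4% (1.08, adjusted p = 0.214). Chromosome 4 had 1 peak and 61 candidates, and the Y had 1 peak and 997 candidates (odds ratio 0.0722, Fisher adjusted p = 0.000153). Unplaced sequences had 86 peaks, 4.37% against 2.73% (odds ratio 1.63, Fisher adjusted p = 0.000153), with odds ratios of 4.24 in the list of replicate 2 and 2.14 in that of replicate 1. The calls for 2L and 2R ended in the conservative set (Fisher adjusted p = 0.155 and 0.121), in the stronger part by signal (0.249 and 0.641) and in the list of replicate 2 (0.923 and 0.790). That for 2L also ended in the list of replicate 1 (0.174) and against the strongest 20000 candidates (0.954). The X passed the test in the list of replicate 1 (odds ratio 1.19, Fisher adjusted p = 0.0229). It also passed against the strongest 20000 candidates (odds ratio 1.81, Fisher adjusted p = 8.04e-18). The Y did not pass it in the list of replicate 1 (odds ratio 0.625), in that of replicate 2 (0.494) or against the strongest 20000 candidates (0.508).

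Genes of the trachea and epidermis, dorsoventral and mesoderm, and cytoplasmic ribosomal protein lists carried peaks more often than other genes, and chemoreceptor genes less often. A peak lay nearest to 11.8% of the 12275 protein-coding genes that were nearest to any candidate. Of the 14 genes of trachea and epidermis, 8 carried a peak (57.1%, odds ratio 10.03, Fisher adjusted p = 0.000271), among them *rib* (signal value 161, 2R 19272121 to 19272500, intron), *vvl* (155), *shn* (129) and *trh*, which directs tracheal fate (100.7). Of the 21 dorsoventral and mesoderm genes, 10 did (47.6%, odds ratio 6.84, Fisher adjusted p = 0.000271), with *tin*, needed for heart development, at 255 (3R 21378678 to 21378847, promoter), *Doc2* at 155, *bin* at 153 and *Mef2*, a muscle regulator, at 120. Of the 73 cytoplasmic ribosomal protein genes, 25 did (34.2%, odds ratio 3.95, Fisher adjusted p = 7.39e-06), with *RpS27* at 290 (3R 25247417 to 25247615, promoter), *RpL34b* at 282, *RpL7* at 222 and *RpL32* at 214. Of the 171 chemoreceptor genes, 5 did (2.92%, odds ratio 0.223, Fisher adjusted p = 0.000271), of which *Gr89a* (116) had a peak in both replicates' lists. A peak can lie far from the start it is assigned to, as that of *vvl* did, at 33854 bp. All p-values are from Fisher's exact test, two-sided, with Benjamini-Hochberg adjustment over the 18 lists. In the list of replicate 1 alone the ribosomal protein call did not hold (11 genes, odds ratio 1.79, Fisher adjusted p = 0.145) and trachea and epidermis was at 6.39; in that of replicate 2 ribosomal protein was at 6.48 and chemoreceptor, with 1 gene, at 0.0737. By gene body the odds ratios were lower for dorsoventral and mesoderm (2.96, Fisher adjusted p = 0.0481) and for trachea and epidermis (4.44), which was at 5.0 in the conservative set. Against random lists matched on candidate number the trachea and epidermis list had 2.50 times the expected count with a permutation adjusted p of 0.0558, and dorsoventral and mesoderm 2.36 times with 0.0480.

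Signalling genes passed the same test in the optimal set, but not in every alternative. Of the 20 genes of receptor tyrosine kinase signalling, 8 carried a peak (odds ratio 5.01, Fisher adjusted p = 0.00374), with *aos*, an Egfr inhibitor, at 233 (3L 16480518 to 16480644, intron), *S* at 220, *ths*, a fibroblast growth factor gene, at 199 and *aop* at 190. Of the 13 Notch signalling genes, 5 did (38.5%, odds ratio 4.69, Fisher adjusted p = 0.0258), with *numb* at 214 and *neur* at 124. Of the 14 segment polarity genes, 6 did (42.9%, odds ratio 5.63, Fisher adjusted p = 0.00885), with *nkd* at 157 and *ptc*, the Hedgehog receptor gene, at 143. Against matched random lists the permutation adjusted p was 0.187 for receptor tyrosine kinase signalling, 0.141 for Notch signalling and 0.290 for segment polarity, and in the list of replicate 2 the Fisher adjusted p of the last 2 was 0.422 each (odds ratios 2.26 and 2.07). In the list of replicate 1 Notch signalling was at 8.22. Over 10 alternative settings, some chosen after seeing the data, receptor tyrosine kinase signalling passed in 9. Notch signalling and segment polarity passed in 4 each. These calls ended in the conservative set (Fisher adjusted p = 0.0744 and 0.0800) and with peaks found in both replicate lists (0.339 each).

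Of the 14 Hox and homeotic genes in the background, 7 carried a peak (odds ratio 7.51, Fisher adjusted p = 0.00181), and among 81 homeobox genes 18 did (22.2%, odds ratio 2.15, adjusted p = 0.0183). In the Hox list *bcd* (signal value 105) was the gene with a peak in both replicates' own lists. In the homeobox list *tin* (255), *zfh1* (248), *vvl* (155) and *NK7.1* (108) had such peaks. Of 10 alternative settings, some chosen after seeing the data, the Hox call held in 5 and the homeobox call in 2. None of the Hox genes kept a peak once peaks with q above 0.05 were left out (odds ratio 0.51, Fisher adjusted p = 1; a choice made after seeing the data), and in the list of replicate 2 the adjusted p was 0.422 for Hox (odds ratio 2.07) and 1 for homeobox genes (1.01). Against matched random lists Hox genes had 2.26 times the expected count (permutation adjusted p = 0.122) and homeobox genes 1.09 times (0.989).

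The remaining lists did not pass the test in the optimal set. Eye development genes, the setting in which *ro* is best known, had 5 of 24 (20.8%, odds ratio 1.97, 95% interval 0.735 to 5.29, Fisher adjusted p = 0.249), with *aop* at 190. Heat shock genes had 4 of 13 (odds ratio 3.33, Fisher adjusted p = 0.0862), with *Hsp27* at 372 and *Hsp83* at 203, and midgut, fat body and haemocyte genes had 4 of 13 (adjusted p = 0.0862), with *Hnf4* at 89.2. Pair-rule genes had 3 of 12 (Fisher adjusted p = 0.222), with *slp2* at 317. Neural transcription factors had 5 of 30 (Fisher adjusted p = 0.470), with *zfh1* at 248, and neuronal differentiation genes 2 of 16 (adjusted p = 1), with *elav* at 353. Muscle structural genes had 3 of 16 (Fisher adjusted p = 0.477), gap and anterior-posterior genes 2 of 15 (adjusted p = 0.735) and cuticle protein genes 2 of 61 (odds ratio 0.253, adjusted p = 0.0778). By gene body, heat shock (odds ratio 5.91, Fisher adjusted p = 0.0250) and cuticle protein genes (0 of 61, 0.0477, adjusted p = 0.000876) passed, and heat shock genes also passed against genes with a promoter candidate, a choice made after seeing the data (6.29, adjusted p = 0.0354).

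**Figure D3:**
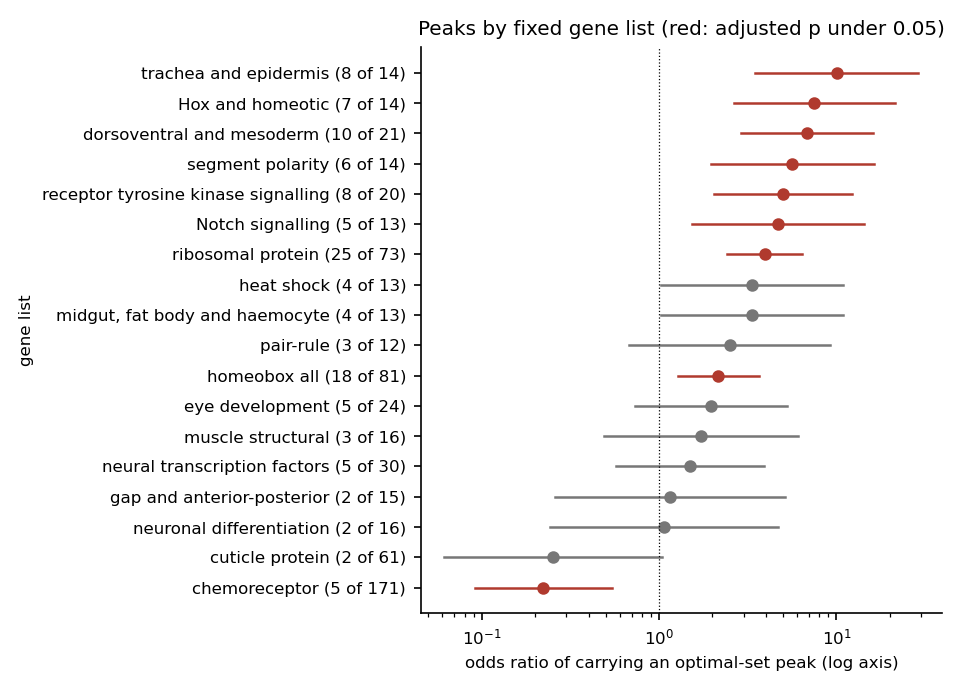
Odds ratio (log axis) of carrying an optimal-set peak for the genes of each fixed list against all other background genes, with 95% intervals, and the count of members with a peak in brackets. Red lists have an adjusted p under 0.05; trachea and epidermis stands highest at 10.03 and chemoreceptor lowest at 0.223.

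The TAATTA word, the core of many homeodomain sites, was more frequent at summits than beside them. It lay within 50 bp of the summit of 193 of 1883 peaks (10.3%, 8.96 to 11.7) and in 95 windows of the same length 300 bp to the right (5.05%; exact McNemar test, two-sided, adjusted p = 1.4e-08). Summit windows were also richer in A and T, at 65.6% ± 10.8 (SD, n = 1883) against 55.6% ± 9.95 in the right flank. In shuffled summit windows that kept every dinucleotide count, TAATTA lay in 12.2% on average, above the 10.3% observed. So the excess over the flank was not an excess over base composition. TTTATG, a Caudal and Abd-B type site, lay in 13.3% of summit windows against 10.6% of flanks (McNemar exact adjusted p = 0.0434), a call that ended in the conservative set (adjusted p = 0.120) and in the list of replicate 2 (1.17 percentage points, adjusted p = 0.675). In the list of replicate 1 the difference was 5.92 points for TTTATG and 8.87 for TAATTA, against 2.71 and 5.20 in the optimal set. GAGAG, the GAGA factor site, was rarer at summits, with 9.82% against 15.7% (McNemar exact adjusted p = 3.15e-07). Neither TTTATG nor GAGAG was set against shuffled windows, so whether base composition accounts for their differences was not tested. TAATGG, CAGGTA, TATCGATA, CACGTG, GATAAG and ATTTGCAT did not pass the test in the optimal set, with McNemar exact adjusted p from 0.134 to 0.585. In the list of replicate 2, TATCGATA (1.95% against 0.292%) and CACGTG (0.486% against 2.33%) passed, each with a McNemar exact adjusted p of 0.00123. Both also passed with 100 bp windows (McNemar exact adjusted p = 0.0321 each), CACGTG (0.0194) and TAATGG (0.0434) against the left flank, and ATTTGCAT in peaks above the median signal (0.0383).

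**Figure D4:**
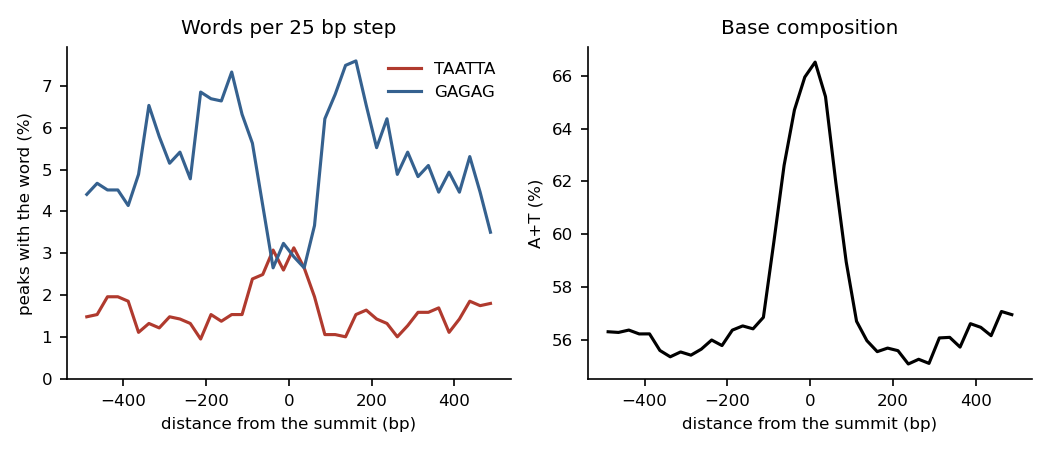
Left, share of optimal-set peaks (%) with TAATTA (red) or GAGAG (blue) in steps along the distance from the summit (bp). Right, mean A and T content (%) over the same distances, which is highest at 66.5% beside the summit, while GAGAG dips there.

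The *ro* gene itself (FBgn0003267) lies on 3R from 26876771 to 26881171 on the minus strand, and 8 optimal-set peaks lay over it or within 20 kb. The 2 with summits inside *ro* overlapped each other. That at 26876887 to 26877266 had a signal value of 67.6 (rank 1717 of 1969) and that at 26877098 to 26877477 had 18.3 (rank 1894). Both summits also lay in *CG5500*, the nearest gene by its start, and neither peak was in a replicate's own list. The strongest of the 8 was at the promoter of *ball*, a chromatin kinase gene (142, rank 553), followed by a *T48* intron peak nearest to the start of *Ets97D* (139), and others lay at *Lerp* (113), *T48* (96.9 and 78.6) and *ms(3)K81* (80.8). The conservative set had 9 peaks in this span, replicate 1 had 6 and replicate 2 had 5, none with a summit in *ro*. The labels do not say how much *ro* sequence the transgene holds, and reads from a further copy would not be set apart in these lists.

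**Figure D5:**
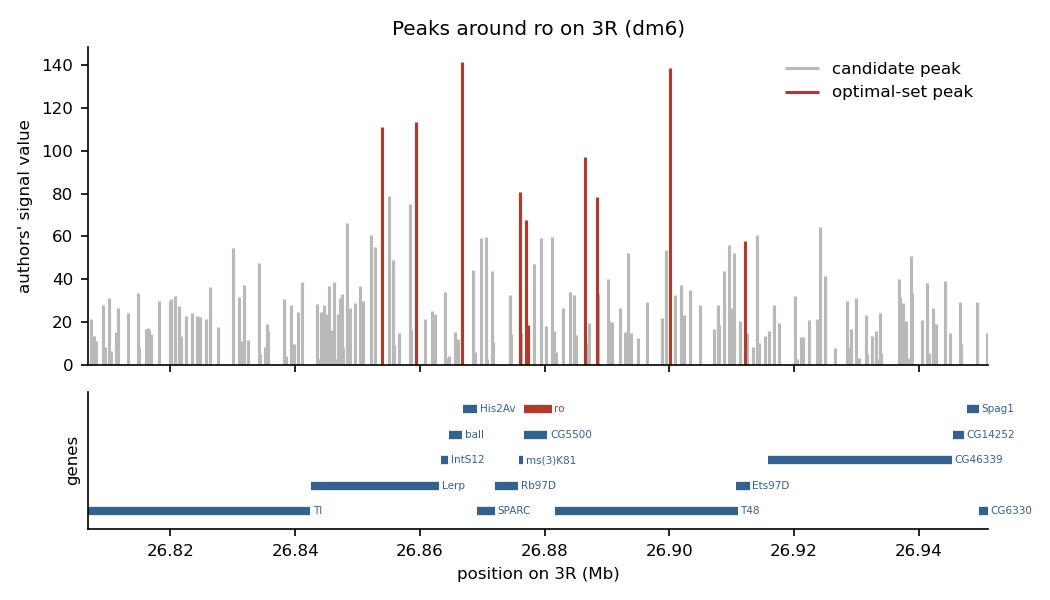
Signal value (y) of candidate peaks (grey) and optimal-set peaks (red) by position on 3R (Mb, dm6), above the protein-coding genes of the region with *ro* in red. The strongest optimal-set peak within 20 kb of *ro* is at *ball*, with a signal value of 142.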

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

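The tests of the low signal values in the optimal set, of the ranks of A and T words and of both accounts of the peaks around *ro* were chosen after the patterns were seen; those of the replicate lists and of the shuffles were written before.

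The ranked list over both replicates held 144 peaks that passed the IDR threshold of 0.01 and were absent from the optimal set. Of these, 80 were on unplaced sequences and 64 on the chromosome arms. The 64 were counted among the candidates in the location tests. The ranked list lies outside the main measurement and no control sample was analysed here to set it against. The strongest of the 64 was nearest to *cbt*, at 2L 480926 to 481246, with a signal value of 1096, which only *Ugalt* exceeded in the optimal set. Others were nearest to *Lk6* (673.7), *larp* (508.2), *tara* (452.4) and *trx* (367.7). These genes were named after their values were seen, and why the peaks were left out was not tested.

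Some thresholded peaks had very low signal values. All 92 optimal-set peaks with a signal value under 30 (100%) overlapped a stronger candidate, against 36.5% of the candidates under 30 outside the set and 0.906% of optimal-set peaks at or above it. In the 2 replicate lists all 85 peaks under 20 did (100%). These values are consistent with the account that a weak peak takes the reproducibility score of a stronger overlapping peak, which may also apply to the second peak inside *ro*. No biological explanation was tested.

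TAATTA was more frequent at summits than in flanks, and Rough is a homeodomain protein. Among the 14 words of 3 A and 3 T, counting a word and its reverse complement together, TAATTA ranked 14 by its summit to flank ratio (2.04, against 3.40 for ATATTA). Its share of summit windows, 10.3%, lay at or below that of all 100 dinucleotide shuffles (permutation, one-sided p = 1.0). In the strongest 500 peaks the share was 12.8%, against a shuffled mean of 16.5%. The right flank held TAATTA in 5.05% of windows, against 4.22% when shuffled (permutation, one-sided p = 0.0495). Base composition of the summits could therefore account for the excess over the flank, and these tests argue against TAATTA sites beyond it at summits. Binding to other sequences, or indirect binding, stays open.

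The span around *ro* was dense in peaks. In the 60 kb centred on *ro* there were 9 optimal-set peaks, and 0.13% of the other 60 kb windows with a peak held as many. Without peaks that overlap a stronger candidate there were 8, and the share was 0.198%. The windows overlap, were not matched on gene density, and the density itself prompted this count. It therefore cannot decide whether the peaks cluster by chance. The median signal of the 62 candidates outside the optimal set was 26.5, above that of 99.6% of other windows (97.8% in replicate 1 and 99.98% in replicate 2); with the 9 peaks counted in, as first computed, it was 28.8, above 99.9%. The level was uneven, with medians of 18.3 to 36.9 over steps of 10 kb against 19.3 in the middle window of the genome. The 99.6% is consistent with a further copy of the region on the transgene, which the labels do not describe, and binding by Rough at its own locus may equally add to it and was not tested.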

How the results depend on the processing

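The promoter excess, the higher promoter signal, the replicate overlap, the TAATTA excess over the flank and the lists of dorsoventral and mesoderm and of chemoreceptor genes kept their direction and passed the test under every alternative run for them, dorsoventral and mesoderm only just by gene body (2.96) and against matched lists (2.36). Taking peaks above the median signal left 984, a count fixed by that rule. For each value below that changed, the cause was not tested. Rank agreement was 0.56 in the conservative set, itself selected by IDR. The number of chromosome classes that passed, unplaced sequences among them, fell from 5 to 3 in the conservative set and 3 in the stronger part by signal, and was 2 to 4 when a replicate was left out. The number of lists that passed, 9, became 5 with peaks found in both replicate lists, 3 against matched random lists, and 5 to 8 when a replicate was left out. All other reversals were in values that did not pass the test, except Hox. With peaks of q above 0.05 left out, a choice made after seeing the data, Hox was 0.51, gap 0.48, eye 0.64, neuronal 0.99 and muscle 0.45 (odds ratios), and GATAAG -0.3 (percentage points). In this setting Hox, gap and muscle had 0 members with a peak. So had gap and muscle in the stronger part, with peaks in both replicate lists and in the list of replicate 2. By gene body so had gap and pair-rule, and in the conservative set chromosome 4 had 0 peaks. The odds ratios of these cases rest on the constant added for counts of 0. In the conservative set, neural transcription factors were at 1, neuronal genes at 0.60 and chromosome 4 at 0.97. In the stronger part, gap was 0.44, eye 0.60, neural 0.98, neuronal 0.92, muscle 0.42 and GATAAG -0.1. By gene body, gap was 0.22, pair-rule 0.24, neural 0.98 and muscle 0.98. With peaks in both replicate lists, gap was 0.57, eye 0.77, neural 0.61 and muscle 0.54. With a background of genes that have a promoter candidate, also chosen after seeing the data, neuronal was 0.63. Against matched lists (observed over expected), gap was 0.65, eye 0.97, neural 0.95 and neuronal 0.70. Against the strongest 20000 candidates, 3L was 0.93 and chromosome 4 was 0.85. With 100 bp windows TAATGG was -1.4 and GATAAG -0.3. Leaving out a replicate gave 0.95 to 1.06 for 3L, 0.43 to 1.47 for gap, 0.43 to 1.91 for neural, 0.60 to 0.83 for neuronal, 0.37 to 0.68 for muscle, and -0.5 to 1.1 for TAATGG. Among the other single classes, lists and words, 238 values kept direction and side, 42 no longer passed and 12 newly passed. Depth is unknown, and with 2 libraries the precision of the peak lists cannot be given.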

Other observations

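The tests of Polycomb group and mitochondrial ribosomal protein genes were chosen after the strongest peaks were seen; that of divergent genes was written before its result was seen.

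Many promoter peaks lay between genes transcribed away from each other. A summit between a minus-strand and a plus-strand protein-coding start, each within 500 bp, was found for 269 of 869 promoter peaks (31.0%) and for 3.87% of 17816 promoter candidates, an odds ratio of 11.14 (95% interval 9.47 to 13.1; Fisher's exact test, two-sided p = 3.87e-143). A looser form was computed first by mistake and corrected to match the written prediction after its value was seen; it did not ask that the summit lie between the starts and gave 6.14. The excess was there at each distance from the nearest start, with odds ratios of 11.3 at up to 50 bp, 11.8 at 50 to 100 bp, 9.57 at 100 to 200 bp and 5.31 at 200 to 500 bp. Candidates may also include promoters not in use in the embryo. Open chromatin at divergent promoters may therefore account for part of this excess of 11.14, and neither was tested.

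Polycomb group genes drew attention because *ph-p* was among the 20 strongest peaks. Of 17 such genes, 5 carried a peak. The strongest were nearest to *ph-p* (808), *Psc* (512.5, 4198 bp from its start), *E(z)* (275) and *ph-d* (243), each in both replicates' lists. For the 17 genes the odds ratio was 3.13 (95% interval 1.10 to 8.88, Fisher's exact test, two-sided p = 0.0416, adjusted p = 0.0832 over the 2 lists). Without *ph-p* the odds ratio was 2.50 (Fisher's exact p = 0.110), so whether these genes may carry peaks more often is left open. Mitochondrial ribosomal protein genes, noticed through *mRpL41*, had 6 of 58 (odds ratio 0.86, 95% interval 0.370 to 2.01, Fisher's exact p = 1), so an excess was not seen and is left open.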
